A study of Mus musculus with 6 samples.

How the data were processed

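RNA was measured in the cortex of mouse embryos of embryonic day 12.5 (strain C57BL/6), in 3 libraries labelled wild type (WT) and 3 labelled as conditional knockouts of both Hdac1 and Hdac2 (cKO). Per the labels' protocols, cortex was dissected on ice, RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit. The promoter of the recombinase, the deleted exons, litters, library strandedness and sequencing batches are not given in the sources used here. The labels do not say that the 3 libraries of a group came from separate embryos, so p-values measure the spread between these libraries, which may be in part technical.

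Per the submitters' processing notes, base calls were converted with bcl2fastq 1.8.4, and the tools listed are STAR 2.5.4b, featureCounts 1.6.1, R 3.4.1 and DESeq2 1.22.1 with the mouse genome build mm10. The annotation used for counting and any filter on rows are not given in the sources used here. One table of 14379 rows was used. Per the file headers, it holds FPKM (fragments scaled to transcript length and sequencing depth) for each of the 6 libraries. The authors' deposited table also gives the mean normalized count of each row, the authors' log2 fold change, p-value and FDR. The FDR is missing for 4509 rows. The columns of the table are named HC-1, HC-8, HC-10, HM-5, HM-13 and HM-16, which are not the sample titles. HC was read as control (WT) and HM as mutant (cKO) from the letters alone, before the values of Hdac1 and Hdac2 were looked at. Which column is which replicate of its group is not given, so libraries are called here by their column names.

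The deposited FPKM values were not scaled to library totals. Each FPKM was multiplied by the row's mean normalized count and divided by its mean FPKM. The result was then divided by a step fitted for each library, the inverse of its size factor. After this, 100% of values in each library were whole numbers of reads, within 0.001 of a read. These recovered reads total 10998247 in HC-1, 11922665 in HC-8, 10345264 in HC-10, 10023061 in HM-5, 11473715 in HM-13 and 9712556 in HM-16 over the rows of the table, and the size factors in the values run from 0.804 (HM-13) to 1.19 (HC-8). The totals cover the rows of the table, not all reads sequenced.

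A symbol with several rows was represented by the row with the highest mean normalized count, a choice made after the table was seen; 1950 of 12041 symbols have more than 1 row. The design had been written for a table of counts, with a fallback for normalized values, and the fallback was used. Genes with an FPKM of at least 1 in at least 3 libraries (9359 symbols) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and group as the only term. Benjamini-Hochberg adjusted p-values under 0.05 were called changed, and "rose" and "fell" are used for such genes only. A positive log2 fold change means higher in cKO. Because of the pseudocount of 1, log2 fold changes understate the change of genes with low FPKM; the ratios of mean FPKM given beside them carry no pseudocount. FPKM is given as mean ± SD over 3 libraries. DESeq2 and edgeR were not run, since the design reserved them for deposited counts. The recovered reads could have served them, but limma's voom on these reads was the only count-based alternative run.

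Most genes named were fixed by a rule before the data were examined. Members of lists called without HM-13, Cdkn1b, Mcm2, Jag1, Rps24, Ttr and the genes of the other observations were named after their values were seen. The rule takes Hdac1 and Hdac2, and the 10 genes that rose most and the 10 that fell most among those called, with a mean log2 CPM of at least 1 and no overlap between the groups. It leaves out predicted genes, clone names, pseudogenes, Xist, Tsix and Y-linked genes. It then takes in each fixed list up to 4 called members with the smallest p, or up to 2 members where none was called. Fixed at the same time were 35 gene lists from textbook knowledge of the embryonic cortex, HDAC1/2 complexes, signalling, cell cycle and stress, of other cell types and of RNA quality. The 26 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. Camera with an estimated correlation and fry, which tests a list's members without comparing them with other genes, were alternatives. Lists of Hox genes, germline genes and mitochondrially encoded transcripts have no member among the rows used and are not analysed here.

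Gene positions are those of GENCODE M21 on GRCm38, in which 10349 of 12041 symbols have a gene of that name, and numbers of RefSeq mRNAs per gene come from a RefSeq gene table in which 10235 symbols were found. The fit was tested on simulated counts drawn from the mean levels, size factors and median dispersion of these libraries. Among 9310 genes simulated for the comparison of cKO with WT, 98.9% of 2-fold and 68.4% of 1.5-fold changes were recovered, 8.19% of calls were false and 0 had the wrong sign. With no change simulated, 0 genes were called. A list raised 1.5-fold passed camera, as did 1 other list, which shares 3 members with it. All simulated genes had the same dispersion and were drawn independently. These rates therefore do not cover genes that vary more or lists whose members vary together. Alternatives were other pseudocounts, filters, scalings and thresholds, voom, and each library left out in turn. Quantile normalization, totals without the ribosomal RNA row Rn45s, robust empirical Bayes, all rows of the table and a covariate for the libraries high in Xist were chosen after seeing the data, as was the count of list members without HM-13. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.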

Results

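The transcriptome of the embryonic cortex was compared between 3 WT libraries (HC-1, HC-8 and HC-10) and 3 cKO libraries (HM-5, HM-13 and HM-16). In the cKO, the genes for the histone deacetylases HDAC1 and HDAC2, which remove acetyl groups from histones as catalytic subunits of corepressor complexes, are conditionally deleted. The comparison asks which transcripts differ when both enzymes are lost in the developing brain at embryonic day 12.5. The recovered reads total 9712556 to 11922665 per library. One cKO library, HM-13, stood apart from the others: 29.7% of its reads lie in the ribosomal RNA row Rn45s, against 0.506% to 2.48% in the other 5 libraries. Xist was high in 1 library of each group (155 FPKM in HC-8 and 105 FPKM in HM-16) and at most 0.0943 FPKM in the other 4.

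Transcripts of both targeted genes were about 4-fold lower in the cKO libraries. Hdac1 (ENSMUST00000102597; chromosome 4, 129516104 to 129542713, GRCm38) had 212, 197 and 193 FPKM in the WT libraries and 45.5, 61.0 and 47.4 FPKM in the cKO libraries, a mean of 201 ± 9.82 against 51.3 ± 8.46 FPKM (SD, n = 3 each). Its log2 fold change was -1.96 (SE 0.11, adjusted p = 0.000307). Hdac2 (ENSMUST00000019911; chromosome 10, 36974544 to 37001889) had 134, 216 and 272 FPKM in WT and 37.6, 61.7 and 47.5 FPKM in cKO, with a log2 fold change of -2.03 (SE 0.27, adjusted p = 0.00441). The cKO means were 25.6% of WT for Hdac1 and 23.6% for Hdac2, over 852 to 5800 reads per library for Hdac2 and 985 to 4949 for Hdac1. A second Hdac2 row (ENSMUST00000105510) had 6.62 ± 0.21 FPKM in WT and 7.46 ± 0.81 FPKM in cKO (n = 3 each). The deleted exons are not given in the labels, and each value is a single one for its row, without exon detail, so the remaining reads cannot be assigned to undeleted exons or to undeleted cells.

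**Figure D1:**
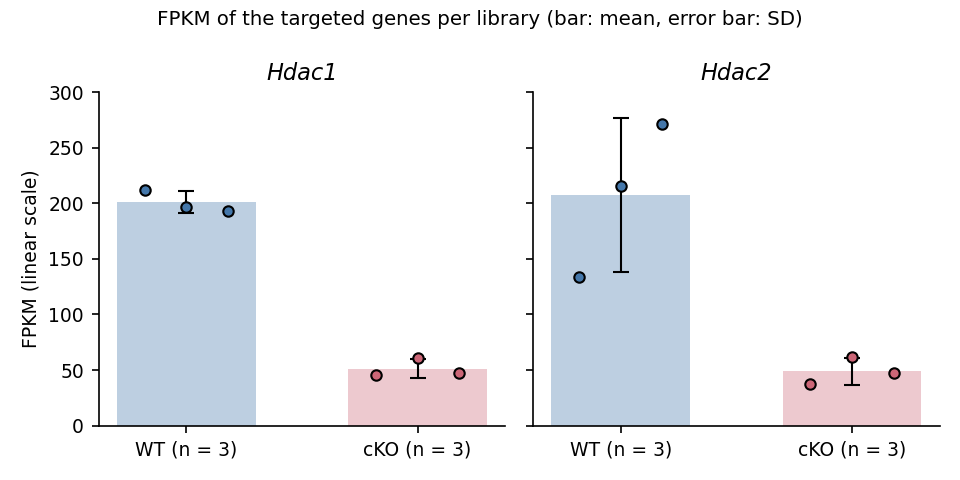
FPKM of Hdac1 and Hdac2 (vertical axis, linear) in the 3 WT and 3 cKO libraries. Points are libraries in the order HC-1, HC-8, HC-10 and HM-5, HM-13, HM-16, bars are group means and error bars are SD; the highest cKO value of either gene, 61.7 FPKM, lies below the lowest WT value, 134 FPKM.

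Beyond the targets, the transcripts that rose most were low or near background in WT. Fam131c went from 0.906 ± 0.274 FPKM in WT to 11.4 ± 2.45 FPKM in cKO (12.6-fold; log2 fold change 2.69, SE 0.18, adjusted p = 0.000622; n = 3 each). Prr15 rose from 6.37 ± 0.21 to 39.7 ± 5.38 FPKM, a 6.24-fold change. Rhpn2 rose 7.31-fold, and Gchfr, the feedback regulator of GTP cyclohydrolase, rose 6.46-fold. Smtnl2 (6.41-fold), the lysine-degrading enzyme Aass (5.08-fold) and the MAP kinase phosphatase Dusp9 (4.25-fold) followed. The antigen peptide transporter subunit Tap2 rose 9.53-fold from 0.407 ± 0.206 FPKM, the MHC class I gene H2-Q4 rose 3.80-fold to 28.3 ± 5.48 FPKM, and the link protein gene Hapln4 rose from 0.166 ± 0.071 to 2.90 ± 0.69 FPKM.

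The transcripts that fell most included abundant ones. Fabp7, the brain fatty acid binding protein of radial glia, fell from 825 ± 123 to 311 ± 103 FPKM (37.8% of WT; log2 fold change -1.44, SE 0.22, adjusted p = 0.00643; n = 3 each). Fgf15, a secreted growth factor, fell from 16.95 ± 9.05 to 3.25 ± 0.658 FPKM (19.15% of WT), and the AP-2 family transcription factor Tfap2e fell from 4.47 ± 1.36 to 0.33 ± 0.0479 FPKM. The guidance protein Draxin (38.7% of WT), the secreted neurexophilin Nxph4 (42.3%), the cell surface protein Emb (40.2%), the ammonium transporter Rhcg (28.6%) and the small heat shock protein Hspb8 (40.9%) also fell. The homeobox gene Vax1 was 9.06, 9.06 and 4.52 FPKM in the WT libraries HC-1, HC-8 and HC-10 and 0, 1.49 and 3.42 FPKM in the cKO libraries HM-5, HM-13 and HM-16 (adjusted p = 0.0412). The histone gene Hist1h2ao was lower (40.3% of WT, adjusted p = 0.0437), but its reads can be shared with near-identical histone genes. The calls of Vax1 and Hist1h2ao were each lost in 5 of the 6 fits with 1 library left out (highest adjusted p = 0.107 and 0.137) and with voom (adjusted p = 0.0576 for both), and that of Hspb8 was lost without HM-16 (adjusted p = 0.0536).

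Of 9359 genes tested, 1685 (18%) changed in the cKO, 900 of them higher and 785 lower, by a median absolute log2 fold change of 0.50. Larger changes were mostly rises: of the 149 genes with an absolute log2 fold change of at least 1, 128 were higher and 21 lower. The 3 cKO and the 3 WT values did not overlap for 3661 genes (39.1%, where chance gives 10%). In the authors' deposited table, 1909 rows have an FDR under 0.05 (1045 higher and 864 lower), and of the 1596 changed genes for which that table gives any FDR, 1462 have one under 0.05 with the same sign. The count of 1685 was sensitive to single libraries: it was 1103 without HC-1, 888 without HC-10, 511 without HM-5 and 545 without HM-16, and it was 497 when library totals, which include the Rn45s reads of HM-13, replaced the size factors. The number of genes past 2-fold depends on the pseudocount, being 297 with a pseudocount of 0.1 and 33 with one of 5. It was 333 with voom and 94 without HM-16. Rises made up 53.4% of the 1685 changed genes. In the other settings their share ran from 45.4% without HC-8 to 63.3% without HC-1, and it was 49.7% after quantile normalization.

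**Figure D2:**
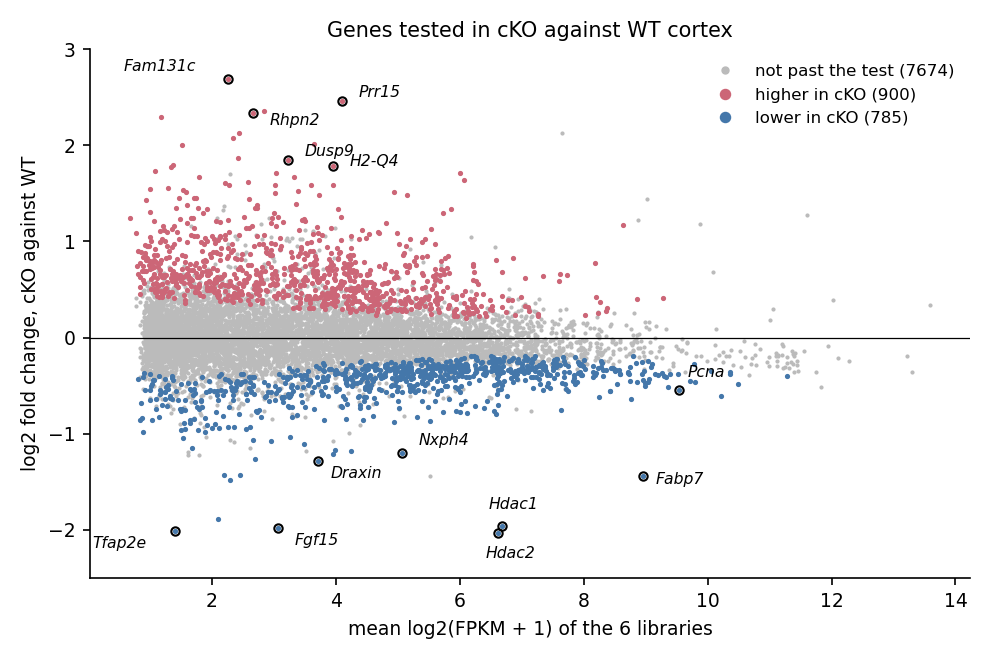
Log2 fold change of cKO against WT (vertical axis) and mean log2(FPKM + 1) over the 6 libraries (horizontal axis) of the 9359 genes tested. Red points are the 900 genes higher in cKO, blue points the 785 lower, grey points genes not past the test; circled genes are Hdac1, Hdac2 and others named in the text.

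Markers of cortical progenitors changed in both directions. Of 15 radial glia genes tested, 3 rose and 1 fell (5 and 1 adjusted over the list alone). The neural transcription factors Sox3 (168 ± 7.85 to 267 ± 46.9 FPKM, 1.59-fold) and Emx2 (158 ± 13.7 to 240 ± 48.9 FPKM, 1.52-fold) were among those that rose, and Fabp7 fell. Of 12 genes of intermediate progenitors, the neurogenic precursors of the cortex, 1 fell: the antiproliferative gene Btg2 went from 70.3 ± 5.23 to 45.0 ± 6.97 FPKM (adjusted p = 0.0106). Of 13 genes of cortical projection neurons, 0 passed limma's test over all genes or over the list alone, 5 had an unadjusted p under 0.05 and 2 passed with voom; their median log2 fold change was -0.36 (camera adjusted p = 0.129). The neuronal transcription factor Bhlhe22 had 26.9 ± 11.3 FPKM in WT and 12.2 ± 1.09 FPKM in cKO (adjusted p = 0.0533), and the microtubule regulator Stmn2 had 110.5 ± 17 and 72.9 ± 20.1 FPKM (adjusted p = 0.0617). The counts of these groups depended on single libraries. Without HC-8, Bhlhe22 passed (adjusted p = 0.00669) as the 1 neuronal gene that fell, and without HM-5 or HM-16 0 radial glia genes rose. Without HM-13, the library rich in ribosomal RNA, 5 of the 13 neuronal genes fell, which were Tbr1, Stmn2, Gap43, Slc17a6 and Tubb3 (all but Stmn2 named outside the rule after their values were seen), and the list passed camera (adjusted p = 0.00129), while 4 of the 12 intermediate progenitor genes fell (Btg2 and, also named outside the rule, Dll3, Neurog1 and Insm1) and 6 of the 15 radial glia genes rose. HM-13 also had the highest Hdac1 and Hdac2 values of the cKO libraries, so these differences cannot be assigned to its ribosomal RNA. The neuronal list passed without HM-13 at the preset correlation of 0.01, whereas its estimated correlation with all 6 libraries was 0.477. Camera with an estimated correlation gave an adjusted p = 0.937 for each of the 26 lists in the fit of all 6 libraries. Emx2 lost its call in 5 of the 6 fits with 1 library left out (highest adjusted p = 0.129), Sox3 without HM-5 or HM-16 (highest adjusted p = 0.0651), and Btg2 without HM-5 (adjusted p = 0.0527).

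Some genes of DNA replication fell in the cKO libraries. Of 14 G1/S genes tested, 5 fell and 0 rose (likewise adjusted over the list alone): the replication clamp Pcna (903 ± 81.0 to 617 ± 17.6 FPKM, 68.3% of WT; adjusted p = 0.00616), the ribonucleotide reductase subunit Rrm1 (72.6%), and the replicative helicase subunits Mcm7 (76.6%), Mcm3 (85.9%) and Mcm2 (86.6%), the last named outside the rule after its value was seen. The list as a whole did not pass camera (adjusted p = 0.310). Of 16 G2/M genes, 1 fell, the mitotic motor Kif11 (87.6% of WT, adjusted p = 0.0482), and 0 passed over the list alone. The cyclin Ccnd1, in the list of Wnt targets, fell from 122 ± 14.0 to 71.6 ± 10.7 FPKM (58.7% of WT, adjusted p = 0.00756). The CDK inhibitor Cdkn2c rose from 14.2 ± 2.02 to 23.3 ± 1.49 FPKM, and the other one tested, Cdkn1b, also named outside the rule, did not pass (adjusted p = 0.840). Of 14 p53 target genes, 3 rose and 0 fell (likewise over the list alone), with a camera adjusted p = 0.159: the stress-induced Sesn2 (2.97 ± 0.13 to 7.89 ± 1.94 FPKM, 2.65-fold), the death receptor Tnfrsf10b (2.11-fold) and the pro-apoptotic Bbc3 (1.53-fold). Mcm3, Mcm2 (adjusted p = 0.0496 with all libraries) and Kif11 lost their calls in each of the 6 fits with 1 library left out (highest adjusted p = 0.139, 0.160 and 0.169), Mcm7 and Tnfrsf10b in 3 of them (highest adjusted p = 0.0720 and 0.0772), and Bbc3 without HM-5 (adjusted p = 0.0546). Pcna, Ccnd1, Sesn2 and Tnfrsf10b stayed past the threshold with library totals as scaling, whereas Rrm1, Mcm7, Mcm3, Kif11, Cdkn2c and Bbc3 did not.

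Genes of the Notch pathway, which maintains neural progenitors, went both ways: 3 of 14 rose and 2 fell (5 and 3 over the list alone; camera adjusted p = 0.888). The ligand gene Jag2 rose from 7.496 ± 1.44 to 14.6 ± 2.41 FPKM (1.95-fold), the ligand gene Jag1 rose from 14.8 ± 1.12 to 20.4 ± 2.78 FPKM (named outside the rule after its value was seen) and the target gene Hey1 rose 1.31-fold. The target gene Hey2 fell from 13.0 ± 3.57 to 5.69 ± 0.20 FPKM (43.8% of WT) and the feedback inhibitor Nrarp fell to 77.4% of WT. Of 7 Wnt target genes, Ccnd1 fell and the Wnt antagonist Nkd1 rose (1.69-fold, adjusted p = 0.0451). Of 8 hedgehog pathway genes, 0 passed with limma or voom and 1 had an unadjusted p under 0.05; the coreceptor Cdon had 106 ± 20.8 FPKM in WT and 80.5 ± 10.3 in cKO (adjusted p = 0.111), and Gas1 had 285 ± 27.3 and 238 ± 36.2 FPKM (adjusted p = 0.171). Of 8 genes of apical junctions and polarity, the atypical protein kinase C gene Prkci rose 1.33-fold and the catenin gene Ctnna1 fell to 76.8% of WT. Hey2, Nrarp and Ctnna1 kept their calls with each library left out; Jag2 and Prkci lost theirs without HM-5 or HM-16 (highest adjusted p = 0.0610 and 0.0658), Hey1 without HC-10, HM-5 or HM-16 (0.0755), and Nkd1 and Jag1 each in 5 of 6 fits (0.142 for both).

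Of the 26 lists tested with camera, the cytosolic ribosomal protein genes were the 1 that passed. All 33 tested members had a log2 fold change below 0, with a median of -0.25; 5 passed the test over all genes and 8 over the list alone (camera adjusted p = 4.82e-06). With an estimated correlation the list did not pass (adjusted p = 0.937), nor with fry's directional test (adjusted p = 0.168); fry's mixed test, of change in either direction, gave an adjusted p = 0.0321. Rps4x fell from 2878 ± 279 to 2174 ± 110 FPKM (75.5% of WT, adjusted p = 0.0310) and Rpl27 from 1197 ± 112 to 941 ± 57.7 FPKM (78.6%). Rps18 (80.7%), Rpl13a (74.3%) and Rps24 also fell, but their WT levels of 60.4 ± 2.66, 24.3 ± 3.08 and 1.14 ± 0.13 FPKM lie far below that of Rps4x. Rps18 and Rpl13a have 2 rows each, and Rps18 did not pass with voom (adjusted p = 0.0610). Rps24 was named outside the rule after its value was seen. It lost its call in each of the 3 leave-one-out fits that tested it (highest adjusted p = 0.145). The median stayed below 0 under each scaling run; after quantile normalization it was -0.09 and no list passed. Without HM-13 the list still passed camera (adjusted p = 1.71e-05), with 3 members fallen. The number of fallen members ranged from 0 (without HC-1, HC-10 or HM-5, and with library totals) through 1 without HM-16 and 13 with voom to 20 without HC-8.

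**Figure D3:**
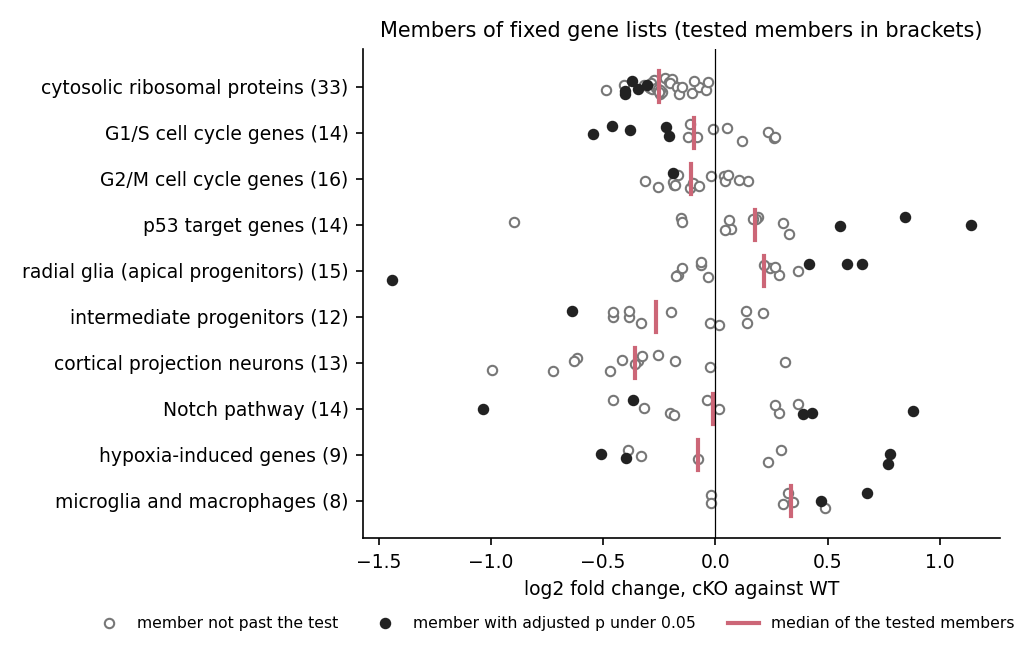
Log2 fold change of cKO against WT (horizontal axis) for the tested members of 10 fixed gene lists. Filled points passed the test with an adjusted p under 0.05, open points did not, and the red bar is the median of the list; all 33 ribosomal protein genes lie left of 0.

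Among proteins that work with HDAC1 and HDAC2, changes were small. Of 18 partner genes of the Sin3, NuRD and CoREST complexes, 1 rose and 3 fell (2 and 4 over the list alone; camera adjusted p = 0.775). Sap30l rose 1.34-fold, and Chd3 (79.7% of WT), Rbbp7 (78.2%) and Rbbp4 (249 ± 4.47 to 216 ± 8.66 FPKM, 86.8%) fell. Of 5 other histone deacetylases tested, Hdac8 rose 1.29-fold (adjusted p = 0.0244), and of 6 histone acetyltransferases, Kat8 fell to 73.7% of WT (adjusted p = 0.0344). Sap30l kept its call with each library left out. Chd3, Rbbp7, Rbbp4, Hdac8 and Kat8 each lost theirs in at least 3 of the 6 fits (highest adjusted p = 0.0907, 0.106, 0.168, 0.0913 and 0.128).

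Genes held back in non-neuronal cells by the repressor REST changed in both directions: of 10 tested, the neurofilament genes Nefl (9.39 ± 2.12 to 15.6 ± 1.08 FPKM) and Nefm (1.61-fold) rose and the adhesion molecule L1cam fell (63.3% of WT), against 3 up and 3 down over the list alone. Of 12 imprinted genes, 2 rose, Igf2r (1.58-fold) and the noncoding Meg3 (1.52-fold), and Mest fell (48.8% of WT). Hypoxia-induced genes also moved apart, with Egln3 (log2 fold change 0.78) and Ndrg1 (0.77) up and the glycolytic enzyme Pgk1 (789 ± 35.8 to 554 ± 17.2 FPKM, 70.2% of WT) and Bnip3 (75.3%) down among 9 tested. Of 8 genes of the integrated stress response, Trib3 rose 2.02-fold and the asparagine synthetase gene Asns fell to 70.2% of WT (3 and 2 over the list alone). Of 5 immediate early genes, Dusp1 fell to 80.9% of WT. None of these 5 lists passed camera (adjusted p = 0.728 for REST targets and imprinted genes, 0.888 for hypoxia, 0.915 for the stress response and 0.827 for immediate early genes). With 1 library left out, Meg3, Egln3, Pgk1, Bnip3 and Asns kept their calls in each fit, and Nefl, Nefm, L1cam, Igf2r, Mest, Ndrg1, Dusp1 and Trib3 did not (highest adjusted p = 0.0788, 0.119, 0.115, 0.0777, 0.0777, 0.0773, 0.164 and 0.0686).

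Markers of other cell types gave few calls, and many of them could not be tested. Tested were 2 of 19 diencephalon and midbrain genes, 2 of 13 astrocyte and oligodendrocyte genes, 5 of 16 ventral genes and 4 of 10 Cajal-Retzius genes. For epithelium these numbers were 3 of 10, for endothelium 5 of 12 and for hem and choroid 9 of 15. They were 8 of 13 for microglia, 7 of 10 for erythroid cells and 9 of 11 for meninges. Lists with few tested members say little about the tissue they mark. Of 8 genes of microglia and macrophages, Tyrobp (8.92 ± 1.13 to 14.9 ± 2.06 FPKM, 1.67-fold, adjusted p = 0.0150) and the complement gene C1qb (1.41-fold, adjusted p = 0.0170) rose and 0 fell (camera adjusted p = 0.129); Tyrobp lost its call without HM-16 (adjusted p = 0.0625) and C1qb in 3 of 6 fits (highest adjusted p = 0.0703). Of 2 astrocyte and oligodendrocyte genes tested, Mbp rose 1.61-fold (adjusted p = 0.0351; lost in 4 of 6 fits, highest adjusted p = 0.130). With limma and with voom, 0 tested genes passed among 5 of the ventral telencephalon and GABAergic neurons, 4 of Cajal-Retzius cells, 9 of the cortical hem and choroid plexus, 2 of the diencephalon and midbrain, 5 of endothelium and pericytes, 9 of meninges and mesenchyme, 7 of erythroid cells and 3 of epithelium. An unadjusted p under 0.05 was seen for 2 Cajal-Retzius genes, 2 diencephalon and midbrain genes and 1 epithelial gene, and for 0 in the other 5 lists. Some passed with 1 library left out: Krt8 and Krt18 without HC-8 (adjusted p = 0.0477 and 0.0250), Cdh5, Ndnf and Lhx9 without HC-1 (0.0479, 0.0415 and 0.0455) and Barhl2 without HM-13 (0.0213). Over the list alone both diencephalon and midbrain genes passed, Lhx9 (7.91 ± 0.91 FPKM in WT and 5.85 ± 0.43 in cKO) and Barhl2 (8.69 ± 3.72 and 3.69 ± 3.03 FPKM). The ventral gene Dlx2 varied as much within groups as between them (adjusted p = 0.402). It had 3.74, 38.3 and 26.5 FPKM in HC-1, HC-8 and HC-10 and 1.43, 11.8 and 13.1 FPKM in HM-5, HM-13 and HM-16. Genes of the cortical hem and choroid plexus also varied within WT. Ttr, named outside the rule after its values were seen, had 118, 145 and 0.0769 FPKM in HC-1, HC-8 and HC-10. Its cKO values were 64.5, 68.4 and 27.1 FPKM. Rspo3 had 56.2, 55.6 and 8.62 FPKM in these WT libraries and 41.05 ± 7.93 FPKM in cKO. The lack of calls in this list therefore does not show that hem and choroid tissue was alike across libraries. Of 17 replication-dependent histone genes 0 passed with limma or voom, none with an unadjusted p under 0.05, and 16 had their highest value in HM-13, where the median was 64.4 FPKM against 2.63 to 6.25 FPKM in the other 5 libraries. The Y-linked genes Kdm5d and Eif2s3y did not pass (adjusted p = 0.944 and 0.979); Eif2s3y had 0.133 FPKM in HC-8 and 0.214 FPKM in HM-16, and 69.0 to 89.0 FPKM in the other 4 libraries.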

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

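Hdac1 and Hdac2 stayed lower and past the threshold under each setting in which they were fitted, with log2 fold changes of -2.09 to -1.88 for Hdac1 and -2.31 to -1.80 for Hdac2 when 1 library was left out. No named gene past the test changed sign under any setting. Of 69 named genes past the test, 33 kept the call in each leave-one-out fit that tested them; Tap2, Hapln4 and Tfap2e were tested in only 3 of these 6 fits, since the filter then removes them. With 1 library left out, 511 to 1773 genes changed (284 to 961 higher and 220 to 812 lower), 94 to 171 of them at least 2-fold, and 2 to 6 lists passed camera. Without HM-13 the count was 1773, of which 1359 were among the 1685. With library totals in place of size factors, 497 genes changed (301 higher, 196 lower), 379 of them shared with the 1685, and 4 lists passed; with totals that leave out Rn45s, 1744 genes changed and 2 lists passed, so the loss follows the Rn45s reads of HM-13. At an adjusted p under 0.01, 482 genes changed (298 higher, 184 lower). Genes past 2-fold numbered 297 with a pseudocount of 0.1 and 33 with one of 5, and 333 with voom, where the cause was not tested. Voom called 1911 genes, 1603 of them shared with the 1685. The number of lists past the test was 2 with a covariate for Xist-high libraries, 0 after quantile normalization, 0 with an estimated correlation and 0 with fry's directional test, where the main result is 1; fry's mixed test, of change in either direction, passed 16 of the 26 lists; the cause was not tested. Quantile normalization, totals without Rn45s, robust empirical Bayes, all rows, the Xist covariate and list counts without HM-13 were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. Planned fits with edgeR, including its other normalizations and robust dispersion, and with DESeq2 were not run. The design reserved them for deposited counts, although the recovered reads could have served. A replicate block was not part of the main design and could not be run for want of replicate numbers. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, the real one with 1685; the highest other gave 1, and 10 splits are too few for a share under 0.05. Depth limits low genes most: Fam131c rests on 11 to 224 reads per library and Hapln4 on 4 to 132.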

Other observations

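The tests on antigen presentation genes were chosen after their values were seen, as were the comparison windows elsewhere in the genome and the list of genes nearly silent in WT; the tests around the targeted loci and on transcripts per gene were written down before their results were seen.

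Several genes of antigen presentation besides Tap2 and H2-Q4 rose in the cKO libraries. Of 30 such genes, 18 were tested: 8 rose, 1 fell and 9 did not pass. Among those that rose, Tap2, H2-Ab1, H2-Q5, H2-Q7 and Psmb8 had WT means under 1 FPKM and met the filter through their cKO values. Genes that low in both groups were not tested, so the share of genes that rose is shaped by the filter. The list was drawn up after these values were seen and holds the genes that prompted it, so no test of the list is given. The class II gene H2-Ab1 rose from 0.435 ± 0.054 to 4.76 ± 0.0895 FPKM, the class I genes H2-D1 from 6.50 ± 0.69 to 16.5 ± 2.93 FPKM and H2-Q7 from 0.778 ± 0.126 to 4.12 ± 0.82 FPKM, and the light chain gene B2m from 56.7 ± 8.26 to 79.5 ± 2.17 FPKM (n = 3 each). H2-Q5 and Psmb8 rose too, though Psmb8 lost its call in each of the 3 leave-one-out fits that tested it (highest adjusted p = 0.121) and B2m lost its call without HC-10, HM-5 or HM-16 (highest adjusted p = 0.0672), while H2-M5 fell from 3.15 ± 0.355 to 1.02 ± 0.0660 FPKM. Further genes were nearly silent in WT and present in each cKO library: the retinal and ventral forebrain homeobox gene Vax2 had 0, 0 and 1 reads in HC-1, HC-8 and HC-10 and 65, 31 and 61 reads in HM-5, HM-13 and HM-16, the forkhead gene Foxi3 had 2 reads over the WT libraries and 55 over the cKO libraries, and Amn had 3 and 41 reads.

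Of the 18 antigen presentation genes tested, 11 lie on chromosome 17, and of the 7 on other chromosomes 1 rose, B2m. Of the 8 that rose, 7 lie in the MHC on chromosome 17, where inbred strains differ in sequence. More microglia in the cKO libraries are argued against as the whole cause for most of these 7, whose median log2 fold change was 1.52 (selected for having risen), since the highest of the 8 microglia markers was 0.68 (Tyrobp) and their median 0.34. This does not cover Psmb8 (0.51) or the list as a whole, whose 18 tested members had a median of 0.47, and a change of state of microglia was not tested. B2m lies on chromosome 2 (adjusted p = 0.0167), so strain DNA linked to the MHC on chromosome 17 does not include it. Its log2 fold change was 0.42 to 0.60 with 1 library left out, but its call was lost in 3 of these 6 fits. Whether B2m rose therefore stays uncertain, and an indirect effect of such strain DNA was not tested. For the 7 genes on chromosome 17, strain DNA cannot be told apart from an effect of the loss of HDAC1 and HDAC2, a candidate explanation. Of 82 other genes between 33 and 38 Mb, 19.5% changed against 18.6% elsewhere (one-sided Fisher p = 0.460). The 95% interval of the odds ratio (1.06, 0.57 to 1.86) is too wide to decide.

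Of the genes named that changed, Sesn2, Tfap2e, Rbbp4 and C1qb lie within 10 Mb of Hdac1, and Hey2 lies within 10 Mb of Hdac2. Within 10 Mb of either target, 49 of 206 genes changed (23.8%), against 18.5% of 8470 genes elsewhere (one-sided Fisher p = 0.0368; odds ratio 1.37, 95% interval 0.97 to 1.91). Around Hdac1 alone, 40 of 159 genes changed (25.2%, one-sided Fisher p = 0.0244, odds ratio 1.48, 95% interval 1.002 to 2.14), a share reached by 7.96% of 7641 windows centred on other genes, and around Hdac2 9 of 47 did (p = 0.515). Changes of at least 2-fold were seen for 10 of the 206 genes near either target, 8 around Hdac1 and 2 around Hdac2. Among all 9359 genes tested, the targets and these 10 included, there were 149. This difference in 2-fold changes was not tested. Strain DNA carried along with the targeted alleles may contribute, but this stays open. The criterion against it, an upper bound under 2 for all changed genes, was met by the pooled regions but not around Hdac1 alone. It had been set too loosely to exclude an odds ratio of 1.37 or 1.48.

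Genes with several annotated transcripts had lower median values in this table. The 10 ribosomal protein genes with 2 or more RefSeq mRNAs had a median of 6.52 FPKM and the 54 with a single one a median of 1531 FPKM, a ratio of 0.00426, with exceptions up to 2053 FPKM in the first group and down to 2.28 FPKM in the second. Over genes with any RefSeq mRNA the gap was smaller, with a median of 1.90 FPKM for 3409 genes against 10.4 FPKM for 6131. This is consistent with reads shared by overlapping transcripts not having been counted; no biological explanation was tested. Mcm7, Ccnd1, Cdkn2c, Bbc3, Nkd1, L1cam, Mest, Mbp, Hdac8, Kat8, Lhx9, Slc17a6, Rps24, H2-Q7 and Eif2s3y, named above, have more than 1 RefSeq mRNA, so their fold changes may rest on part of their reads. The same holds for named genes with several rows, of which only the highest was tested. Meg3 has 4 rows. Chd3, Stmn2, Cdon, Cdkn1b, Ccnd1, Cdkn2c, Kat8, Lhx9, Kdm5d and Hist1h2ao have 2 each, like Hdac2, Rps18 and Rpl13a.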
